A study of Sus scrofa with 12 samples.

How the data were processed

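RNA of porcine subcutaneous preadipocytes, the precursor cells of fat cells, was measured on 12 Agilent arrays of 2 colours. Per the labels' protocols, cells grew in low-glucose medium with serum and were then differentiated in high-glucose medium with insulin (5 µg/ml), dexamethasone (0.25 µM), biotin, pantothenate and octanoate (5 mM). On every array Cy3 carried RNA of cells transfected with an siRNA and differentiated to day 4, and Cy5 carried RNA of untransfected preadipocytes at day 0, a common reference, with 400 ng of RNA labelled for each dye. The 4 groups of 3 arrays received control siRNA or an siRNA against F2RL2, LGR4 or GPR124. For the F2RL2 arrays the titles give F2RL2 and another label field spells the target R2RL2; the titles were followed. Replicate numbers were taken from the titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

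Per the file headers, spots were quantified with Agilent Feature Extraction. The deposited intensity columns used were the median pixel brightness of each spot and of its local background in each channel, with no normalization. The deposited processed signal intensity was background-subtracted, detrended and dye-normalized by that software, per the file headers. The deposited log10 ratio column of the same files gives Cy5 over Cy3 and was used only to check the direction of ratios. The authors' value table holds log2 ratios, which differed from the log2 of processed Cy3 over processed Cy5 by at most 5e-10 on any row. Its scale is therefore log2, its direction sample over reference, and it has no further centring; none of these stays unknown. Its column medians were 0.12, 0.14 and 0.087 for control siRNA replicates 1 to 3, 0.11, 0.13 and -0.089 for F2RL2 siRNA, 0.12, 0.11 and 0.15 for LGR4 siRNA, and -0.25, -0.15 and -0.21 for GPR124 siRNA. The design had assumed mean spot signals and gene names. The files used here hold median signals, which were used in their place, and pair no probe with a gene.

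Signals were background-corrected with normexp (offset 50), log ratios were normalized within each array by loess with the 1417 control spots at weight 0, and turned to Cy3 over Cy5, so that a positive value means more RNA in the transfected, differentiated cells. Spots marked as outliers by the scanner software were left out on the array concerned. Of 43221 probes, 32346 were kept because they lay well above background in the same channel on at least 3 of 12 arrays. Each probe occurs in 1 spot. The fit was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 12 arrays, 1 coefficient per group), with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. Each siRNA group was compared with control siRNA and with the other targeting groups, the 4 groups were compared by an F test, and the control log ratio was tested against 0 for differentiation. Dyes were not swapped and the reference cells were not transfected, so effects of dye and of transfection are part of the differentiation ratio; the siRNA groups share both. The reference counts as 1 sample of undifferentiated cells, and the test against 0 leaves out its own spread.

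None of the 43221 probe identifiers matched the gene and accession tables used here, so 0 probes were named, the targeted genes could not be checked on these arrays, and the 21 gene lists fixed in advance were not analysed here. The rule for named genes had asked for the targets, the largest changes, members of the lists and the genes called the same way in all 3 siRNA comparisons with the smallest maximum adjusted p. Without gene names, only the last part was used, for 2 probes that were higher and 2 that were lower. The largest changes are given without identifiers, among probes called, on the same side of the comparison group's mean on all 3 arrays and well above background on all 3 arrays of the brighter group.

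A set of measures was defined after the data were seen. For each targeting siRNA, probes raised or lowered in differentiation were taken from the mean log ratio of the other 2 targeting groups (adjusted p under 0.05 and an absolute log2 ratio of at least 1), so that no array of the comparison defined its own probes. Their shift was tested with camera at a preset correlation of 0.01, adjusted over 6 sets. The correlations estimated from the data were higher, 0.0958 to 0.227, which makes p-values at the preset too small where they hold. The slope of each array's log ratios on that mean was divided by the control arrays' mean slope to give the share of the differentiation log ratio kept. Since that mean comes from targeting groups, effects that the siRNAs share raise this share. The same shared effects enter the choice of the sets, and can by themselves push raised sets up and lowered sets down. For a probe not well above background on any array of the dimmer group, a bound on the fold was computed per channel after loess and Aquantile, against the lowest signal among probes well above background or the probe's own, whichever was higher; it is open to dye bias.

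Well above background in Cy3 were 24720 to 29381 probes per array. In Cy5 the number was 30350 to 32394 on 8 arrays, 27003 on F2RL2 siRNA replicate 3 and 23594 to 26485 on the GPR124 arrays. No spot was saturated. With 3 arrays per group, the number of arrays limits the precision. The scanner's spike-in controls gave an observed over expected log ratio slope of 0.847 to 0.865. Arrays lay on 3 slides. Slide 1 held the control arrays and F2RL2 siRNA replicate 1, slide 2 the other F2RL2 arrays and LGR4 siRNA replicates 1 and 2, and slide 3 LGR4 siRNA replicate 3 and the GPR124 arrays. Slide was fitted as a fixed and as a random block, and within the slide that held both groups.

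The procedure was tested on simulated data made from 31663 probes with 200 changed in a simulated F2RL2 siRNA comparison. Of the changed probes, 53.7% were called at a log2 change of 0.5, 95.5% at 1 and 100% at 2, and 8 of 31463 unchanged probes were called. A share of 0.7 simulated for GPR124, with the other groups at the control mean, was recovered as 0.6998. Effects shared by the targeting siRNAs were not simulated. Alternatives covered background correction, processed signals, the value table, the normalization, Cy3 alone, the filter, the variance model, the arrays in the fit, slide and replicate blocks, leaving out each array, a fold threshold and other set tests. They were chosen before the data were examined, except array weights by group, leaving out probes with a marked spot, a slide block together with an estimated set correlation, and every use of alternatives on the measures defined after the data were seen. Deviations of same-numbered arrays from their group means correlated over 0.1 in each of 3 pairs for LGR4 and GPR124 siRNA (0.229 to 0.553), which meets the rule for numbers, taken from the titles, that pair samples. The fit had no replicate term, as fixed before the data were examined, and a replicate block was an alternative; in the other comparisons at least 1 pair lay at or below 0.1.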

Results

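The arrays measured which transcripts changed when porcine subcutaneous preadipocytes were differentiated for 4 days, and how this differed with siRNAs against 3 G-protein-coupled receptors. F2RL2 encodes a protease-activated receptor, LGR4 a receptor for R-spondins, and GPR124 an adhesion receptor that takes part in Wnt signalling. Each of the 4 siRNA groups had 3 arrays, and all values are log2 ratios of transfected, differentiated cells over untransfected preadipocytes, given as mean ± SD with n = 3 unless stated. Log ratios correlated at 0.97 to 0.98 across probes within the control group, 0.92 to 0.94 within F2RL2, 0.92 to 0.96 within LGR4 and 0.89 to 0.95 within GPR124. The GPR124 arrays correlated with those of other groups at 0.61 to 0.76. The first principal component, 46.2% of the variance, separated the GPR124 arrays from all others. Probes are not independent replicates, and no probe is paired with a gene in the files used here, so the level of each targeted transcript is not reported.

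**Figure D1:**
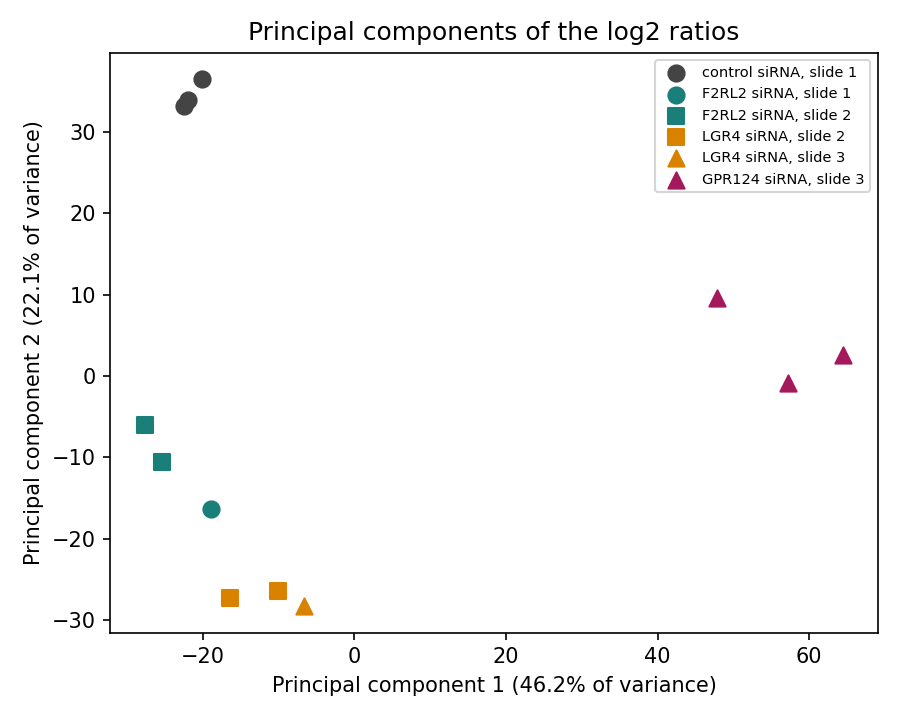
Each point is 1 array, placed by its first (x axis, 46.2% of variance) and second (y axis, 22.1%) principal component of the log2 ratios; colours mark the siRNA and shapes the slide. GPR124 siRNA arrays lie at 47.9 to 64.4 on the first component, and LGR4 siRNA replicate 3, on the same slide, lies at -6.59.

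Differentiated control siRNA cells differed from the undifferentiated reference in 63.2% of the measured probes. Of 32346 probes, 9261 were higher and 11176 lower at day 4 than in the reference (limma, Benjamini-Hochberg). At least a log2 change of 1 was reached by 1171 of the higher and 1835 of the lower probes. The largest rise was 5.96 ± 0.16, a 62.1-fold change (limma adjusted p = 3.66e-13), and the largest fall was -5.49 ± 0.065, or 45.0-fold (adjusted p = 3.66e-13). With the processed signals, the log2 ratios of these probes were 6.51 and -6.15. Differentiation cannot be separated from transfection or dye in these ratios, here or where probes are called raised or lowered in differentiation, because the reference cells were untransfected and dyes were not swapped. With median centring in place of loess, which moved the median of all probes to -0.24, 27.2% of called probes were higher, against 45.3% after loess. With slide as a fixed block, which sets the value at the mean of 3 slides although the control arrays lay on 1, 13560 probes were called.

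With F2RL2 siRNA, 3233 probes were higher and 2570 lower than with control siRNA. Changes of at least 1 on the log2 scale were fewer, 207 higher and 303 lower. The probe that rose most went from 0.097 ± 0.11 to 2.91 ± 0.040, a log2 difference of 2.81 (SE 0.078) or 7.0-fold (limma adjusted p = 3.66e-09). The largest fall was from 4.46 ± 0.41 to 0.70 ± 0.19, a log2 difference of -3.76 (SE 0.32, adjusted p = 8.77e-06). Of 807 probes raised in differentiation, 244 rose, 159 fell and 404 did not pass, with a median log2 difference of 0.11. Of 1322 probes lowered in differentiation, 294 rose, 114 fell and 914 did not pass, with a median of 0.031. Neither set passed camera (adjusted p = 0.0594 and 0.0547; 0.647 for both with an estimated correlation), although with slide as a block both did, at medians of 0.16 and 0.13 (adjusted p = 0.0079 and 0.000208; adjusted p = 0.57 and 0.464 with an estimated correlation). These results changed with single arrays. The raised set passed without control siRNA replicate 2, LGR4 siRNA replicate 2 or 3, or GPR124 siRNA replicate 1 (adjusted p = 0.0319 to 0.0454). The lowered set passed without control siRNA replicate 1 or 3, F2RL2 siRNA replicate 2 or 3, LGR4 siRNA replicate 1, or GPR124 siRNA replicate 1 or 2 (adjusted p = 0.00664 to 0.0496). Both passed without a filter on dim probes (adjusted p = 0.0126 and 0.0103), the raised set with the strict filter (0.0389) and the lowered set with median centring (0.000677). The arrays kept 0.986 ± 0.034 of the differentiation log ratio, a difference from control that was within the spread of arrays (2-sided exact permutation p = 0.7, n = 3 per group). This does not show an unaltered program, since effects shared with the LGR4 and GPR124 groups raise the share. Such effects can also push the raised set up and the lowered set down. Across probes, F2RL2 fold changes correlated with the control differentiation ratio at -0.32, against -0.10 when simulated. Without control siRNA replicate 3 the number of called probes was 3624 instead of 5803, and with median centring it was 2181, of which 69.0% were higher against 55.7% after loess. A slide block gave 4128, and the arrays of slide 1 alone, with 1 F2RL2 array assumed to vary like the controls, gave 8227.

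With LGR4 siRNA, 4424 probes were higher and 3032 lower than with control siRNA. At least a log2 change of 1 was seen in 464 higher and 276 lower probes. The largest rise was from 1.01 ± 0.055 to 5.97 ± 0.038, a log2 difference of 4.96 (SE 0.16) and 31.2-fold (limma adjusted p = 1.42e-09). The probes lowered in differentiation moved up on average, although the set did not pass camera with an estimated correlation. Of 1473 such probes, 720 rose, 117 fell and 636 did not pass, and their mean log ratio was -1.38 ± 0.065 under LGR4 siRNA against -1.70 ± 0.056 in control. The median difference was 0.31 (camera adjusted p = 1.45e-14; adjusted p = 0.153 with an estimated correlation), and 0.39 with slide as a block (adjusted p = 5.9e-17; adjusted p = 0.199 with an estimated correlation). Of 776 probes raised in differentiation, 216 rose, 242 fell and 318 did not pass, with a median of -0.030 (adjusted p = 0.128; 0.647 with an estimated correlation), which was 0.047 with slide as a block (adjusted p = 0.864) and -0.051 with median centring (adjusted p = 0.00626). The share of the differentiation log ratio kept was 0.905 ± 0.050, with slopes of 0.90 to 1.00 against 1.01 to 1.08 on control arrays (2-sided exact permutation p = 0.1, n = 3 per group, the smallest p that 3 arrays against 3 allow). Median centring gave 3576 calls instead of 7456, 74.3% of them higher against 59.3% after loess, and with slide as a block 2711 probes were called. Control and LGR4 arrays shared no slide, so no value within a slide exists.

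With GPR124 siRNA, 7266 probes were higher and 5482 lower than with control siRNA. These were the most calls of the 3 comparisons with control, except with slide as a block. A log2 change of at least 1 was reached by 596 higher and 869 lower probes. The probe that rose most went from -0.61 ± 0.089 to 3.81 ± 0.13, a log2 difference of 4.43 (SE 0.092) and 21.5-fold (limma adjusted p = 1.06e-10). The one that fell most went from 4.46 ± 0.41 to -0.50 ± 0.18, was not well above background on any GPR124 array, and was at least 25.9-fold lower (adjusted p = 2.61e-07). Log ratios were smaller on both sides of the differentiation program. Of 1087 probes raised in differentiation, 646 fell, 157 rose and 284 did not pass, and their mean log ratio was 1.01 ± 0.095 against 1.54 ± 0.012 in control. Of 1430 probes lowered in differentiation, 946 rose, 118 fell and 366 did not pass, and their mean was -1.24 ± 0.086 against -1.74 ± 0.059. Median differences were -0.51 (camera adjusted p = 4.08e-19) and 0.50 (adjusted p = 7.08e-21), each with adjusted p = 0.153 with an estimated correlation. They were -0.43 and 0.57 with slide as a block (adjusted p = 2.37e-13 and 1.48e-21; adjusted p = 0.209 and 0.199 with an estimated correlation). The 2 sides were less equal with median centring, at -0.30 and 0.51 (camera adjusted p = 1.89e-17 and 1.93e-13), and with the processed signals, at -0.42 and 0.67. GPR124 arrays kept 0.712 ± 0.050 of the differentiation log ratio, with slopes of 0.65 to 0.75 against 0.96 to 1.02 on control arrays (2-sided exact permutation p = 0.1, n = 3 per group, the smallest possible). With slide as a block, 2552 probes were called instead of 12748, fewer than the 4128 and 2711 of F2RL2 and LGR4 siRNA under that block, and no slide held both groups. Median centring, which moved the median of all probes to 0.11, gave 73.8% of calls higher against 57.0% after loess, whereas Cy3 alone gave 48.0% higher, a turn of the majority. Per array, 154 to 280 spots were marked as outliers on the GPR124 arrays and 335 on LGR4 siRNA replicate 3, all on slide 3, against 1 to 4 on the other 8 arrays.

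**Figure D2:**
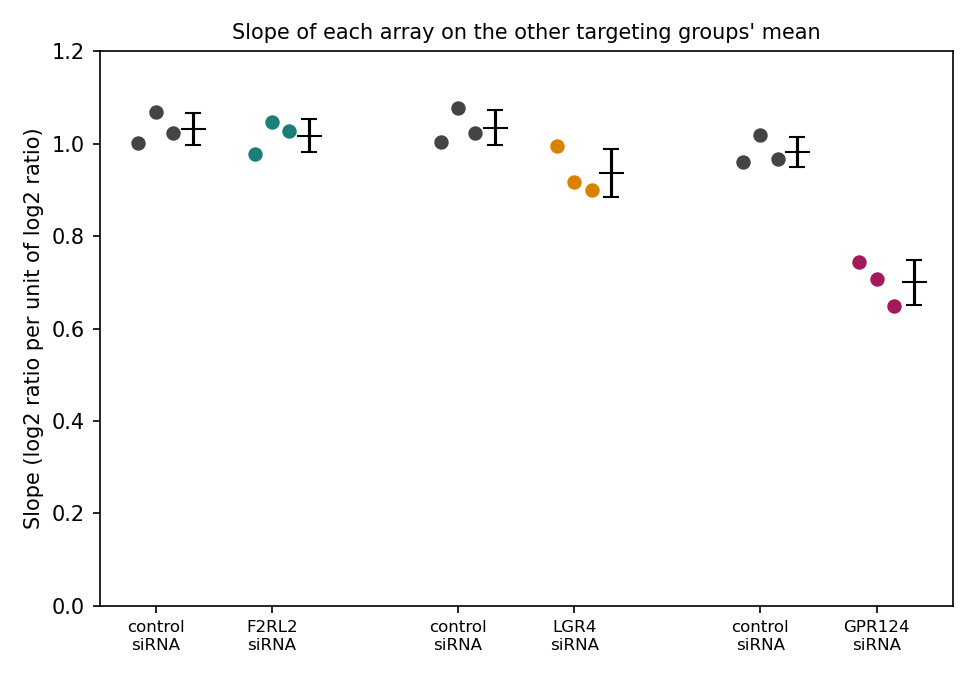
Points are single arrays, and bars the mean ± SD (n = 3); the y axis is the slope of an array's log2 ratios on the mean log2 ratio of the 2 targeting groups not compared, over all probes, drawn for control and for each targeting siRNA. GPR124 siRNA slopes (0.65 to 0.75) lie below those of control (0.96 to 1.02), and F2RL2 siRNA slopes (0.98 to 1.05) overlap control (1.00 to 1.07).

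Among the 4 groups, 16494 of 32344 probes differed by the F test, and 9937 did with slide as a block. Between targeting groups, F2RL2 and LGR4 siRNA differed least in number, with 1795 probes higher and 2709 lower under F2RL2 siRNA. F2RL2 against GPR124 siRNA gave 6236 higher and 7140 lower, and LGR4 against GPR124 siRNA 6129 higher and 6010 lower. At a log2 change of at least 1, F2RL2 against GPR124 had the opposite majority, with 888 higher and 642 lower. At that threshold LGR4 against GPR124 had 846 higher and 319 lower, and F2RL2 against LGR4 113 and 240. For F2RL2 against LGR4, leaving out F2RL2 siRNA replicate 3 gave 2948 calls, Cy3 alone 2427, median centring 1377, a slide block 2615 and the arrays of slide 2 alone 1120. For F2RL2 against GPR124, median centring gave 8758 calls, 35.9% of them higher against 46.6% after loess, and a slide block 5288; Cy3 alone turned the majority, with 55.3% higher. LGR4 against GPR124 gave 7363 calls with median centring, 39.0% of them higher against 50.5% after loess, 7779 with a slide block (52.5% higher) and 3713 on slide 3 alone (59.6% higher), where the single LGR4 array was assumed to vary like the GPR124 arrays. The share higher was 45.8% with the processed signals, 47.8% without GPR124 siRNA replicate 1 and 53.8% without GPR124 siRNA replicate 2.

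**Figure D3:**
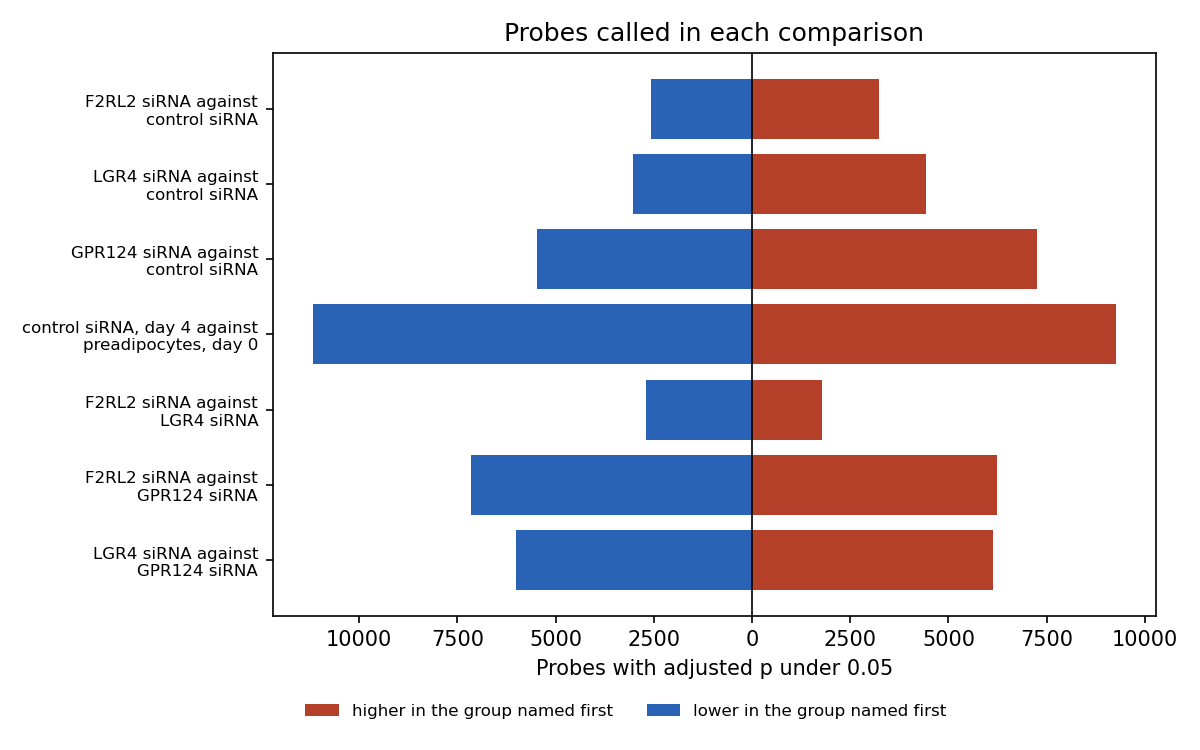
Bars to the right count probes higher in the group named first and bars to the left probes lower in it (x axis, number of probes with adjusted p under 0.05 in limma); each row is 1 comparison. GPR124 siRNA has 7266 higher and 5482 lower probes against control, LGR4 siRNA 4424 and 3032, and F2RL2 siRNA 3233 and 2570.

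The siRNAs shared many called probes. In all 3 comparisons with control, 868 probes were higher and 787 lower, where independent lists of these sizes would share 99.3 and 40.8. Simulated unchanged groups against a shared simulated control group gave 0 shared calls in each of 20 data sets (limma), with at most 1 probe called in a single comparison. All arrays were simulated with independent noise and no slide or culture effect. The simulation therefore cannot tell whether the real control arrays or slides caused overlap. Of the 868 higher probes, 656 were lower and 98 higher in differentiation, and of the 787 lower probes, 658 were higher and 53 lower in differentiation. Over all 32346 probes, 9261 were higher and 11176 lower in differentiation. The control arrays enter both comparisons with opposite sign, so opposite directions are in part built in. The calls on the real arrays all use the same control arrays, which cannot be split, so part of the overlap may come from them. Across probes, fold changes correlated at 0.67 between F2RL2 and LGR4, 0.34 between F2RL2 and GPR124 and 0.48 between LGR4 and GPR124, against 0.50 in each simulated pair. Their covariances were 0.076, 0.050 and 0.082, against 0.0068 in each simulated pair. The correlation between LGR4 and GPR124 was 0.53 with the processed signals or median centring. With slide as a block the 3 correlations were 0.77, 0.50 and 0.61, against 0.76, 0.60 and 0.80 when unchanged groups were simulated and fitted with the block, and the covariances were 0.12, 0.097 and 0.14, against 0.027, 0.027 and 0.047. With differentiation the correlations were -0.32, -0.46 and -0.53 for F2RL2, LGR4 and GPR124 (-0.10 when simulated), and the covariances -0.067, -0.11 and -0.17 (-0.0069 when simulated). A slide block gave covariances with differentiation of -0.114, -0.171 and -0.217, against -0.0207, -0.0309 and -0.0375 when simulated. The total of 1655 shared calls was 1084 without control siRNA replicate 3, 767 with median centring and 555 with slide as a block.

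Of the shared probes, AGPOA3-09980 fell in differentiation to -5.03 ± 0.047 under control siRNA (adjusted p = 5.84e-14). It was at -3.36 ± 0.13 under F2RL2 siRNA, -2.35 ± 0.064 under LGR4 siRNA and -2.86 ± 0.16 under GPR124 siRNA, that is 3.16-fold, 6.39-fold and 4.48-fold above control (limma adjusted p = 5.08e-07, 1.94e-09 and 1.1e-08). AGPOA3-31826 was at -2.01 ± 0.022 in control and at -1.003 ± 0.0095, -0.69 ± 0.063 and -1.10 ± 0.069 under F2RL2, LGR4 and GPR124 siRNA (adjusted p = 1.15e-06, 2.67e-08 and 4.21e-07). In Cy3 alone its GPR124 difference was -0.16 (adjusted p = 0.656), the opposite direction, so no rise was seen in the sample channel. AGPOA3-02926 rose to 3.81 ± 0.30 in control and was at 0.42 ± 0.20 under F2RL2 siRNA, where 2 of 3 arrays lay well above background, and at 0.16 ± 0.050 and 0.22 ± 0.13 under LGR4 and GPR124 siRNA. It was not well above background on any array of these last groups and was at least 12.1-fold and 11.1-fold lower than in control (adjusted p = 5e-09 and 6.73e-09). AGPOA3-08743 was not well above background in the reference channel of any control array, so that it was at least 5.99-fold higher in differentiated control cells than in the reference. Its measured log ratio was 2.68 ± 0.040 in control and 0.69 ± 0.094, 0.50 ± 0.13 and 0.58 ± 0.11 under F2RL2, LGR4 and GPR124 siRNA (adjusted p = 1.19e-07, 6.71e-09 and 9.95e-09), and was well above background on 3, 2 and 1 of their 3 arrays. With the processed signals the differences from control of AGPOA3-02926 and AGPOA3-08743 kept direction and passed the threshold, and their sizes, which rest on signals near background, were larger.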

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

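The tests of the slide, of the spike-in slopes and of the arrays that deviate together were chosen after the results were seen. Some probes were called in opposite directions against control by 2 siRNAs, with the difference between those siRNAs called as well. There were 128 such probes for F2RL2 and LGR4, beside 3350 called in the same direction, 1349 for F2RL2 and GPR124, beside 2312, and 1111 for LGR4 and GPR124, beside 3823. Independent lists would give 654.6, 1125 and 1431 opposite calls before the difference is tested. Testing the difference removed none of the observed opposite calls, since a difference of opposite effects exceeds either, so it adds no support. With slide as a block the numbers were 11, 101 and 46, with median centring 20, 233 and 221, with Cy3 alone 67, 761 and 660, and with the processed signals 114, 1356 and 1204.

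GPR124 siRNA arrays stood apart from all others and gave 12748 called probes against control, although only 2552 with slide as a block, where the other siRNAs gave 4128 and 2711 and standard errors for GPR124 rose the most, 2.34 times. A different reference RNA as the cause of the whole pattern is argued against by the channels, since the slope of the Cy5 difference on the log ratio difference was 0.0441 and that of Cy3 was 0.981. Cy5 still differed on these arrays, with 23594 to 26485 probes well above background against 30350 to 32394 on 8 others, and AGPOA3-31826 differed from control by 0.91 in the log ratio and -0.16 in Cy3 alone, so for single probes the reference stays open. Slide 3 stays open. The 1 array of another group on that slide, LGR4 siRNA replicate 3, lay 0.0964 of the way from the other LGR4 arrays to the GPR124 arrays, and 1 array excludes nothing. The knockdown itself, an effect of this siRNA on other transcripts and a difference between cultures also stay open, since the targeted transcript was not measured here.

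GPR124 siRNA arrays kept 0.712 of the differentiation log ratio. Compressed ratios are argued against by the spike-in controls, whose slope was 0.996 of that on control arrays, and dim probes by the 16173 probes of higher mean signal, on which the share was 0.705 ± 0.052. With slide as a block the median differences were -0.43 and 0.57 instead of -0.51 and 0.50 (camera adjusted p = 2.37e-13 and 1.48e-21; adjusted p = 0.209 and 0.199 with an estimated correlation). Median centring gave median differences of -0.30 and 0.51. The slide 3 term rests on the 1 array of another group on that slide, which kept 0.94 of the slope of the other LGR4 arrays, so slide 3 is not excluded. An effect of the siRNA on differentiation and an unequal state of the cultures were not tested and stay open too.

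Control siRNA replicate 2, F2RL2 siRNA replicate 2, LGR4 siRNA replicate 1 and GPR124 siRNA replicate 1 deviated together from their group means, at correlations across probes of 0.198 to 0.619 in 6 pairs, the highest mean (0.438) of 81 choices of 1 array per group. The reference channel is argued against, as Cy3 alone gave a mean correlation 0.224 above that in Cy5 alone and the higher value in 6 of 6 pairs. Position on the slide and replicate number are argued against as the whole cause. The effect of position, of any shape, that came closest to the covariances between groups gave the 6 pairs a mean correlation of 0.054, and that of number gave 0.0179, each below the observed value in 6 of 6 pairs. With same-numbered arrays of other groups outside these 4, their correlations were -0.588 to -0.172 in 8 pairs. Deviations cancel within a group and the 4 arrays were chosen for deviating together, so these negative values are not separate evidence against replicate number. A round of culture or labelling that the labels do not give may also be shared by these arrays, and no biological explanation was tested.

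For each comparison of 2 siRNA groups the 6 arrays have only 10 splits, too few for a share under 0.05. The real split was the 1 with the most calls in every such comparison, with 5803, 7456 and 12748 probes for F2RL2, LGR4 and GPR124 against control and 4504, 13376 and 12139 for F2RL2 against LGR4, F2RL2 against GPR124 and LGR4 against GPR124, and 0 in the highest of the others. For LGR4 against GPR124, whose numbers pair, the 3 other splits that part all 3 pairs gave 0 as well. For the F test, 1 of 100 splits of the 12 arrays, the real one, gave as many probes (16494, highest other 8218). That argues against chance only if all 12 arrays are independent, which the labels do not state. Arrays of a group that shared a culture could give the same outcome whatever the siRNA did. These splits take no account of slide, with which 9937 probes were called as a block.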

How the results depend on the processing

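Array weights and leaving out probes with a marked spot were chosen after seeing the data, as was every test of the differentiation sets and of the kept share. Aquantile leaves log ratios as they are and the value table repeats the processed signals, so neither tests anything further. Under the other alternatives, 160 of 187 counts of called probes stayed within 1.5 times. The alternative of averaging probes per gene and the tests of gene lists were not run, because no probe was named. Signal over background limits bounds on probes that are dim in 1 group.

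Median centring gave 2181 (F2RL2), 3576 (LGR4), 1377 (F2RL2 against LGR4), 8758 (F2RL2 against GPR124) and 7363 (LGR4 against GPR124) calls and 767 in all 3 comparisons; the median SE was 0.14 against 0.097 after loess. Cy3 alone gave 2427 for F2RL2 against LGR4, and turned AGPOA3-31826 under GPR124 siRNA to -0.16; the cause was not tested. Slide as a fixed block gave 2711 (LGR4), 2552 (GPR124), 13560 (differentiation), 2615, 5288 and 7779 (between targeting groups), 9937 by the F test and 555 in all 3 comparisons. Standard errors rose 1.41 to 2.34 times against control, while fold changes correlated at 0.89 to 0.92 with those without the block. The terms of slides 1 and 2 called 3 and 25 probes. The effect of slide 3, which those terms set, was not tested. With few arrays linking the slides, few calls do not show that slide effects were small. As a random block (correlation 0.051), slide gave 5633, 6962 and 11946 calls against control. Slide 2 alone gave 1120 for F2RL2 against LGR4 and slide 3 alone 3713 for LGR4 against GPR124, with fewer arrays. An absolute log2 change of at least 1 left 510, 740 and 1465 calls against control, 3006 in differentiation and 353, 1530 and 1165 between targeting groups.

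Outside LGR4 against GPR124, correlations of the deviations of same-numbered arrays were -0.588 to 0.198. Those of control with F2RL2 siRNA were all positive, 0.0459 to 0.198. Deviations cancel within a group, so low or negative values do not show that same-numbered arrays shared no culture. Over all groups, 3 of 12 arrays correlated best with their own number. With the replicate block, 4850, 6525 and 11898 probes were called against control. For LGR4 against GPR124 the replicate block gave 11298 calls instead of 12139. That block was fitted over all 12 arrays, with the same replicate effect for every group. It is therefore not a paired fit of LGR4 and GPR124 alone.

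Leaving out 1 array gave 3624 to 5979 calls for F2RL2 against control (lowest without control siRNA replicate 3), 2948 to 4023 for F2RL2 against LGR4 (lowest without F2RL2 siRNA replicate 3) and 1084 to 2035 in all 3 comparisons (lowest without control siRNA replicate 3).

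The share of the differentiation log ratio kept by GPR124 was 0.648 with Agilent's processed signals and 0.648 with the value table, and that of F2RL2 was 0.934 with median centring. For F2RL2, the median of probes raised in differentiation passed camera at 0.11 without a filter, 0.13 with the strict filter and 0.16 with a slide block, and fry at 0.11; that of lowered probes passed at 0.12 with median centring, 0.031 without a filter and 0.13 with a slide block. Leaving out 1 array gave 0.097 to 0.13 and -0.023 to 0.072; the sets stayed short of the threshold in 8 and 5 of 12 fits. For LGR4 the raised probes passed at -0.051 with median centring. With an estimated correlation the sets of F2RL2 did not pass (adjusted p = 0.647 each; 0.57 and 0.464 with a slide block as well), and those of LGR4 (0.31) and GPR124 (-0.51 and 0.50) did not pass (adjusted p = 0.153 each), nor did they with a slide block as well (0.39, -0.43 and 0.57; adjusted p = 0.199, 0.209 and 0.199), a setting added after seeing the data. The cause was not tested for these. Of 545 values of named or largest-change probes under alternatives, 544 kept direction and stayed past the threshold. These include 29 values with Aquantile and 29 with the value table, which test nothing further. As folds, 14 of 29 moved by over 1.5 times with the processed signals.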
